A study of Mus musculus with 12 samples.

How the data were processed

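Cells were sorted by flow cytometry from mouse cutaneous squamous cell carcinomas, and RNA was extracted with Trizol and made into Illumina TruSeq v2 libraries from 100 ng of total RNA, per the labels' protocols. The deposited tables hold raw counts of reads per gene, which the authors made before deposit. FastQC and STAR and the mouse genome mm10 (GRCm38) are named, without versions, in the submitters' processing notes. The counting tool, the strand setting and the annotation release are not given in the sources used here, so reads shared between similar or overlapping genes cannot be told apart, and members of families such as Sprr, Lce, keratin, Fc receptor and H2 genes are uncertain in that respect. The series text mentions that earlier RNA-seq data were combined with these libraries, and a threshold of 0.01 for p. Those data were not used here, and 4 columns of counts that belong to no sample of the series were left out of every step.

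Each table has 53801 gene rows, of which 0 name no gene. Gene IDs were matched to GENCODE M21 on GRCm38, where 53620 were found, and coordinates are from that annotation. In 258 rows the gene name occurs more than once, and these were told apart by ID. In the macrophage table the gene with the ID ENSMUSG00000029378 carries the name Mcub, and it was read by its ID as Areg. Total counts were 27951632 to 35088897 per tumor library and 33704786 to 40041144 per macrophage library. Groups and replicate numbers were taken from the sample titles.

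Counts were tested with edgeR 4.0.16 in R 4.3.3 (trimmed mean of M values, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjustment, threshold 0.05), each comparison on its own 6 libraries. The filter left 13604 genes in the tumor cells and 14988 in the macrophages, which hold 99.9% of all counts. Log2 differences are positive minus negative with their standard errors, and CPM values use the normalized library sizes. The design fixed before the data were examined had no pairing, with the replicate number as a block as an alternative. Whether the numbers pair the samples was then decided from the data, because the labels do not say what a number marks. Deviations from the group means correlated at 0.449, 0.703 and 0.488 between tumor libraries of number 1, 2 and 3 and at 0.688, 0.787 and 0.734 between macrophage libraries. All were over 0.1, so the number was used as a block in both comparisons. In the tumor cells negative replicate 1 correlated at 0.488 with positive replicate 3, above its 0.449 with positive replicate 1. Negative replicate 3 correlated at 0.483 with positive replicate 1. There the pairing separates replicate 2 from replicates 1 and 3, and the values do not show that numbers 1 and 3 each mark a pair. Each macrophage library correlated best with its own number. Paired results are given beside unpaired ones where they differ in call. The paired fit leaves 2 residual degrees of freedom and the unpaired fit 4. The biological coefficient of variation was 0.188 without and 0.0764 with the block in the tumor cells, and 0.302 and 0.102 in the macrophages.

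There were 34 gene lists fixed before the data were examined, 15 tested in the tumor cells and 26 in the macrophages, with some tested in both. Of the list genes, 0 were unmatched. They were tested with camera (limma 3.58.1, two-sided, preset correlation 0.01, adjusted over the lists of a comparison) and again with the correlation estimated per list. With the estimated correlation 0 lists were called in either comparison, with or without the block. The fry test, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called 1 tumor list (epithelial junctions) and 6 macrophage lists (resident-type, lysosome and lipid, Fc gamma receptors, macrophage, dendritic cell and B cell) without the block, and 0 with it. Each list also has counts of genes adjusted over the list alone.

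Genes were named by a rule fixed before the data were examined. It took the genes behind the sort with Il33 and Il1rl1, the 8 higher and 8 lower genes of largest log2 difference with an adjusted p under 0.05, a mean CPM of at least 10 and non-overlapping groups, up to 4 genes per list with the smallest p, and 4 sex-linked genes. The size part left out predicted genes and antigen receptor segments. Applying that part to the paired fit was decided after seeing the data. Krt1, Tgfb1, Krt14, Cd207, C1qa, C1qb, C1qc, Col3a1 and Areg fall outside the rule and were chosen after their values were seen. The text does not describe every gene that the rule took, and the results of some genes are not reported here.

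The alternatives were DESeq2 1.42.0, other scaling factors, other count filters, the block, an unadjusted threshold and leaving out each library. Added after seeing the data were the paired fits without each pair, the paired fit with DESeq2, the fit without pair 2 and without the block, and sums of tumor replicates 1 and 3. Scripts were tested on simulated counts drawn from the real means and library sizes with 100 genes changed at each fold. The simulated pairs differed as in the data and the dispersions came from the paired fit, so better recovery by that fit was built in. The 3 pairs were treated as separate samples, also in the tumor cells. In the tumor simulation of 13604 genes, the unpaired fit recovered 69% of 2-fold and 92% of 4-fold changes with 0 false calls, and the paired fit 97% and 100% with 33 false calls. In the macrophage simulation of 14988 genes, the unpaired fit recovered 31% and 71% with 0 false calls, and the paired fit 91% and 100% with 23 false calls. The simulated changes were placed in well-counted genes, and the real unpaired macrophage fit called 0 genes, so these shares do not give the recovery in the real libraries. Of 20 unchanged gene sets, camera called 0 in each simulation. The simulated genes were drawn independently of each other. In the tumor libraries the estimated correlation was 0.77 in the cell cycle list and 0.841 in the keratinocyte differentiation list. The simulation therefore does not show how often camera with the preset correlation calls unchanged lists of correlated genes. Tables were handled with pandas 2.3.3 in Python 3.11.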

Results

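RNA was sequenced from cells sorted out of cutaneous squamous cell carcinomas of FVB mice, in 12 libraries that form 2 separate comparisons. The tumor comparison had 6 libraries of basal tumor cells, which were sorted for a YFP lineage mark and for the integrins CD49f and CD29. An mScarlet reporter of TGF-beta signalling divided these cells into 3 positive and 3 negative libraries. The macrophage comparison had 6 libraries of tumor macrophages, sorted for CD45 and F4/80 and divided by surface FceRIa, the IgE-binding chain of the high-affinity IgE receptor, into 3 positive and 3 negative libraries. Total counts ran from 27951632 to 35088897 per tumor library and from 33704786 to 40041144 per macrophage library. Expression is given as CPM (counts scaled to a common library size), and 3 counts, the floor used for a gene with none, correspond to between 0.0749 and 0.107 CPM. This floor covers counting error only. The tests covered 13604 genes in the tumor cells and 14988 in the macrophages. Nothing in the labels says that the replicates came from separate animals or tumors, so the p-values measure the spread between these samples, which may be technical in the tumor cells. In the macrophages replicate 2 had 4 and 6 counts of the X-inactivation RNA Xist and 5972 and 4817 of the Y-linked gene Ddx3y (negative and positive library), and replicate 3 had 16108 and 18122 of Xist and 3 and 6 of Ddx3y, so these replicates came from different mice. Replicate 1 held transcripts of both kinds. Each comparison was fitted without pairing (the unpaired fit) and with the replicate number as a block (the paired fit). Adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

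The tumor comparison asked which genes distinguish carcinoma cells that respond to TGF-beta from those that do not. Genes of keratinocyte differentiation and of epithelial junctions were higher in the reporter-positive cells, and cell cycle genes were lower. These were calls of lists with a preset correlation, and with an estimated correlation the adjusted p was 0.617, 0.242 and 0.59, while 0 of 20 differentiation, 2 of 20 junction and 0 of 24 cell cycle genes passed over all genes in the unpaired fit. The means of the leukocyte and dissociation stress lists were also higher in the positive library of each number. Of their 15 and 14 tested genes, 0 passed over all genes in the unpaired fit, and 3 and 7 rose in the paired fit. Sprr1a, a small proline-rich protein of the cornified envelope, was at 463 ± 410 CPM in the positive cells and 77.5 ± 1.78 CPM in the negative cells (SD, n = 3), with 233, 936 and 219 CPM in positive replicates 1 to 3. Dsp, which encodes desmoplakin of desmosomes, was at 3719 ± 372 against 2406 ± 66.3 CPM. Mcm5, a subunit of the replicative helicase, was at 183 ± 19.6 CPM in the positive and 271 ± 10.7 CPM in the negative cells. Il33, an alarmin of the IL-1 family, was at 43.8 ± 51.6 against 9.94 ± 3.53 CPM, with most of the difference in positive replicate 2.

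In the unpaired fit, 78 genes were higher and 32 lower in the reporter-positive tumor cells at an adjusted p under 0.05. The paired fit called 1450 higher and 999 lower, among them all 110 genes of the unpaired fit with the same sign. In 3830 genes (28.2%) every positive library lay on one side of every negative library, where chance gives 10% for libraries not tied by number, and the 3 other splits that part all pairs gave 2.3% to 5.1%. The splits that keep some pairs together gave up to 17.4%. The other splits were counted after seeing the data. The 3 that part all pairs put libraries of both groups on each side, so any group difference adds to the spread there. Their low shares are therefore no measure of chance. Replicates 1 and 3 of each group were close to each other. Their counts differed with a chi-square per degree of freedom of 3.13 in the negative and 1.65 in the positive cells, against 46.8 to 98.9 for the pairs that include replicate 2, so they differed beyond counting noise. This does not show that they came from separate tumors, since repeat libraries of one tumor can also differ by more than counting noise, and n = 3 counts each library once. With replicates 1 and 3 of each group summed, an alternative added after seeing the data, the unpaired fit called 0 genes higher and 0 lower and the paired fit 691 higher and 244 lower. The unpaired counts fell to 0 higher and 0 lower without negative replicate 1, negative replicate 3 or positive replicate 3, to 1 and 0 without positive replicate 1 and to 8 and 2 without negative replicate 2. They were 391 and 230 without positive replicate 2. Without pair 1, 2 or 3 the paired fit called 1055, 2927 and 803 genes higher and 498, 2802 and 340 lower.

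The size rule named 16 genes in the unpaired fit. Cd200 (ENSMUSG00000022661, chromosome 16, 45382135 to 45409053, GRCm38, GENCODE M21), a surface glycoprotein that restrains myeloid cells, rose by 1.68 ± 0.16 on the log2 scale (SE), from 13.3 ± 2.60 to 42.7 ± 4.49 CPM (SD, n = 3), with an adjusted p of 0.0341. Pcdh1, a protocadherin, rose by 1.91 ± 0.24 (adjusted p = 0.0412) and the serine protease gene Tmprss11b by 1.77 ± 0.20 (adjusted p = 0.0391). Ccnd2, the gene of cyclin D2, rose by 1.28 ± 0.14 (adjusted p = 0.0389), from 64.4 to 157 CPM. Rgs2, Hs3st1, Atg9b and Fam84a rose by between 1.09 and 1.48. Mcm10 (ENSMUSG00000026669, chromosome 2, 4989714 to 5012791), a replication initiation factor, fell by 0.79 on the log2 scale (SE 0.07, adjusted p = 0.0341), from 30.6 ± 1.68 to 17.7 ± 0.726 CPM. The other lower genes named by the size rule were Efemp1, Hlf, Hmgn2, Pmf1, Dnph1, Sapcd2 and Rpa2, the last a subunit of the single-stranded DNA binding complex, with log2 changes from -0.77 to -0.57. Each of these 16 genes was also called in the paired fit. Each lost its unpaired call without negative replicate 1 or 3 or positive replicate 1 or 3 (Cd200 adjusted p = 0.249, 0.25, 0.172 and 0.154) and kept it without positive replicate 2, and without negative replicate 2 Cd200 and Atg9b kept it. With DESeq2 scaling factors the adjusted p of Fam84a was 0.0522, and with upper-quartile factors that of Hlf was 0.056.

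The same size rule was applied to the paired fit after seeing the data, and took larger differences that varied more between replicates. Lce3c (ENSMUSG00000045475, chromosome 3, 92944486 to 92945733), a late cornified envelope gene, rose by 2.70 ± 0.31 in the paired fit (adjusted p = 0.00678), and its unpaired adjusted p was 0.0769. Defb14, an antimicrobial defensin, and Alox12b, a lipoxygenase of the epidermal barrier, rose by 2.61 and 2.39 with the block (unpaired adjusted p = 0.0728 and 0.0834). Both were highest in positive replicate 2, at 43.2 CPM of Defb14 and 67.0 CPM of Alox12b, and without pair 2 they rose by 1.97 and 1.74. Pitx1, a homeobox transcription factor, rose by 2.09 ± 0.09 (paired adjusted p = 0.00149, unpaired 0.225). Krt15 (ENSMUSG00000054146, chromosome 11, 100131758 to 100135928), a keratin of basal and bulge keratinocytes, fell by 1.18 on the log2 scale in the paired fit (SE 0.07, adjusted p = 0.00201), from 58.8 ± 15.2 to 26.4 ± 9.73 CPM, with an unpaired adjusted p of 0.112. Sostdc1, an antagonist of BMP and WNT signalling, fell by 1.17 in the paired fit (adjusted p = 0.00208, unpaired 0.178).

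Of the 15 gene lists fixed for the tumor cells before the data were examined, camera called 6. In the keratinocyte differentiation list, 0 of 20 tested genes passed over all genes in the unpaired fit, 13 were higher when adjusted over the list alone, and 16 rose in the paired fit. The median log2 difference was 1.69, and the camera adjusted p of 7.29e-10 compares with an adjusted p = 0.617 with an estimated correlation. Sprr1a rose by 2.21 ± 0.42 in the paired fit (adjusted p = 0.0199) and by 1.53 without pair 2, the transcription factor gene Grhl3 by 1.80 ± 0.26 and the envelope precursor Ivl by 1.04 ± 0.20. In the epithelial junction list, 2 of 20 genes rose in the unpaired fit, 13 when adjusted over the list alone and 14 in the paired fit (median 0.46, camera adjusted p = 1.48e-10, adjusted p = 0.242 with an estimated correlation). The 2 were Dsp, which rose by 0.63 ± 0.09 (adjusted p = 0.0475), and the tight junction gene Ocln, which rose by 1.73 ± 0.26 from 0.393 to 1.32 CPM. Dsp and Ocln lost these calls when any single library other than positive replicate 2 was left out (Dsp adjusted p from 0.0993 to 0.271), and with upper-quartile factors their adjusted p was 0.06 and 0.0518 (0.0519 for Ocln with DESeq2 scaling factors). Replicate 2 stood apart in both groups. The suprabasal keratin Krt1 was at 166 CPM in negative replicate 2 and at 37.0 and 39.0 CPM in the other negative libraries, and at 257 against 51.7 and 49.1 CPM in the positive ones.

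Cell cycle genes moved the other way. Of 24 tested genes, 0 passed in the unpaired fit, 11 were lower when adjusted over the list alone, and 22 fell in the paired fit, with a median log2 difference of -0.41 (camera adjusted p = 1.58e-13, adjusted p = 0.59 with an estimated correlation). Mcm6 fell by 0.61 in the paired fit (adjusted p = 0.0169), and Pcna, the sliding clamp of DNA polymerase, fell by 0.38 (adjusted p = 0.00977). The unpaired adjusted p was 0.0579 for Mcm5 and 0.0608 for Pcna.

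In the list of TGF-beta targets, 0 of 28 genes passed in the unpaired fit, 3 were higher when adjusted over the list alone and 6 rose in the paired fit, with a median log2 difference of 0.17 (camera adjusted p = 0.0315, adjusted p = 0.765 with an estimated correlation). The cell cycle inhibitor genes Cdkn1a and Cdkn2b rose by 0.66 ± 0.11 and 0.66 ± 0.11 in the paired fit (adjusted p = 0.0147 and 0.0148), and Smurf1, a ubiquitin ligase of the pathway, by 0.43 ± 0.06. In the list of epithelial-mesenchymal transition and invasion genes, 1 of 22 genes rose in the unpaired fit, 1 when adjusted over the list alone and 8 in the paired fit (median 0.23, camera adjusted p = 0.0328, adjusted p = 0.394 with an estimated correlation). The call of the target list was lost without negative replicate 2 (camera adjusted p = 0.382), positive replicate 1 (0.216) or positive replicate 3 (0.116), and that of the transition list without negative replicate 2 (0.115) or positive replicate 2 (0.0962). The gene that rose was Vim, the intermediate filament vimentin, which rose by 0.83 ± 0.08 (adjusted p = 0.0341) from 29.0 ± 1.90 to 51.6 ± 3.71 CPM and lost its call when any single library other than positive replicate 2 was left out (adjusted p from 0.07 to 0.25). In the paired fit the stromelysin gene Mmp10 rose by 0.93 ± 0.10. In the hypoxia and glycolysis list, 0 of 18 genes passed, 1 was higher when adjusted over the list alone and 7 rose in the paired fit (median 0.20, camera adjusted p = 0.00396, adjusted p = 0.765 with an estimated correlation, and 0.0872 by camera without positive replicate 2). Vegfa, an angiogenic growth factor, rose by 0.76 ± 0.12 in the paired fit. Hk2, a hexokinase of glycolysis, rose by 0.95 ± 0.21 there, and by 0.59 without pair 2, and the paired DESeq2 fit did not call it.

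The remaining 9 tumor lists were not called in the unpaired fit. Of the cytokine and growth factor genes, 0 of 22 passed, 1 was higher when adjusted over the list alone, and with the block 10 rose and 2 fell (camera adjusted p = 0.129 without and 0.00162 with the block, adjusted p = 0.454 with an estimated correlation and the block). Of the NRF2 and glutathione genes, 1 of 27 fell in the unpaired fit, and with the block 7 rose and 3 fell. It was Txnrd1, a thioredoxin reductase, which fell by 0.45 on the log2 scale (SE 0.06, adjusted p = 0.0475, and from 0.0873 to 0.271 with any library other than positive replicate 2 left out), whereas the glutathione transferase gene Gsta4 rose by 1.58 ± 0.11 in the paired fit (adjusted p = 0.00227). Of the basal and stem keratinocyte genes, 0 of 16 passed, and with the block 3 rose and 2 fell. Of the interferon genes, 0 of 15 passed and 2 rose with the block. Adjusted over the list alone, the unpaired fit called 0 NRF2 genes higher and 1 lower, 1 basal gene higher and 1 interferon gene higher. The camera adjusted p was 0.926 for NRF2, 0.774 for basal and 0.196 for interferon genes. Camera called the cytokine list without negative replicate 1 (adjusted p = 0.0344) or positive replicate 2 (0.0186), and the NRF2 list without positive replicate 2 (0.0186).

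Markers of other cells and of handling were measured beside these groups. The mean log2 CPM of the leukocyte list was 1.14, 3.07 and 1.02 in negative replicates 1 to 3 and 1.5, 3.52 and 1.35 in the positive ones, so it was higher in the positive library of each number and highest in replicate 2. Of its 15 tested genes, 0 passed in the unpaired fit, 0 when adjusted over the list alone, and 3 rose with the block (camera adjusted p = 0.392 without and 0.00332 with the block, adjusted p = 0.355 with an estimated correlation and the block). Without negative replicate 2 camera called the leukocyte list in the unpaired fit (adjusted p = 0.00367), and without pair 2 its paired call was lost (0.207). The dissociation stress list of immediate early and heat shock genes had means of 8.87, 7.65 and 8.80 in the negative and 9.02, 7.91 and 9 in the positive libraries. Of its 14 genes 0 passed in the unpaired fit, 0 when adjusted over the list alone, and 7 rose with the block (camera adjusted p = 0.401 without and 0.000975 with the block, adjusted p = 0.355 with an estimated correlation and the block). Of the endothelial (9 tested), fibroblast (12) and muscle (2) markers, 0 passed in the unpaired fit, and 1 endothelial and 1 fibroblast marker fell with the block. Adjusted over the list alone, 1 muscle marker was higher and 0 endothelial or fibroblast markers passed (camera adjusted p = 0.373, 0.774 and 0.573 for endothelial, fibroblast and muscle). With 1 library left out the endothelial list was called in 1 case (0.0228 without negative replicate 2) and the stress list in 2 (0.0405 without negative replicate 1 and 0.00883 without positive replicate 2). Median, mean and test differed in sign for 3 tumor lists. These were the basal list (median -0.03, mean 0.11, test down), the NRF2 list (median 0.03, mean 0.12, test down) and the fibroblast list (median 0.09, mean below 0, test down).

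**Figure D1:**
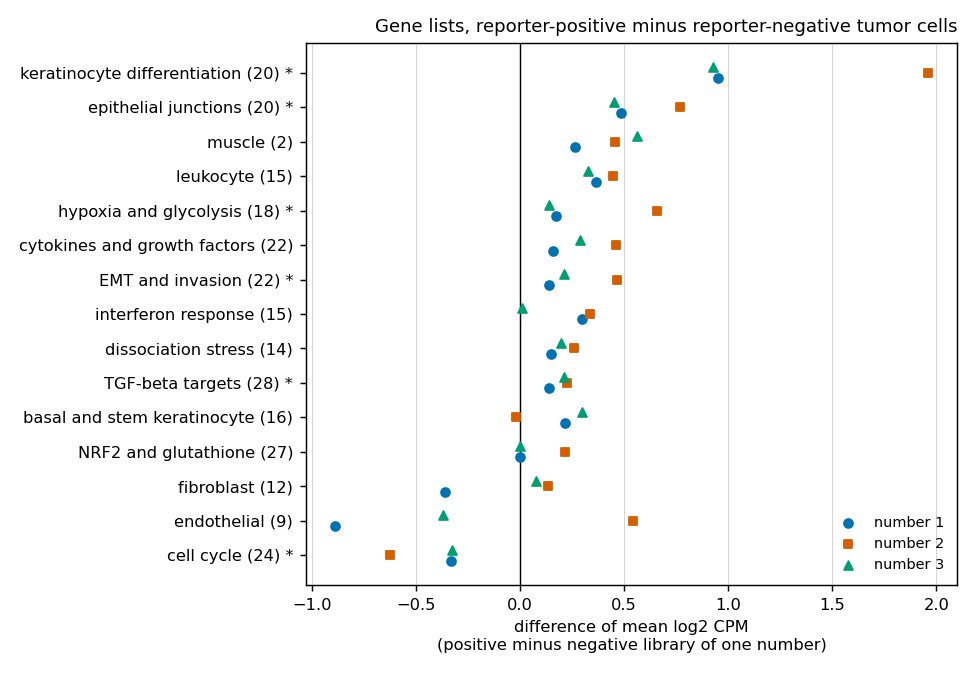
Difference of mean log2 CPM between the positive and the negative tumor library of one replicate number, for each fixed gene list, with 3 points per list and the number of tested genes in brackets. An asterisk marks a camera adjusted p under 0.05 in the unpaired fit. The keratinocyte differentiation list lay at 0.95, 1.96 and 0.93 in replicates 1, 2 and 3, and the cell cycle list at -0.33, -0.63 and -0.33.

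The genes behind the sort were examined in every library. Itga6 (CD49f) was at 1239 ± 12.1 CPM in the negative and 1112 ± 196 CPM in the positive cells, a log2 difference of -0.16 ± 0.13 (adjusted p = 0.589), and Itgb1 (CD29) differed by -0.04 (adjusted p = 0.889). Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718), named as the cytokine the study is known for, was at 8.19, 14.0 and 7.63 CPM in negative replicates 1 to 3 and at 13.9, 103 and 14.0 CPM in positive replicates 1 to 3. Its log2 difference was 2.14 ± 0.86 in the unpaired fit (adjusted p = 0.24) and 1.61 ± 0.42 in the paired fit (adjusted p = 0.0458), and it was higher in the positive library of each number. Without positive replicate 2 the unpaired log2 difference of Il33 was 0.48 (adjusted p = 0.322), and without pair 2 the paired one was 0.81. The paired DESeq2 fit gave Il33 an adjusted p of 0.11.

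**Figure D2:**
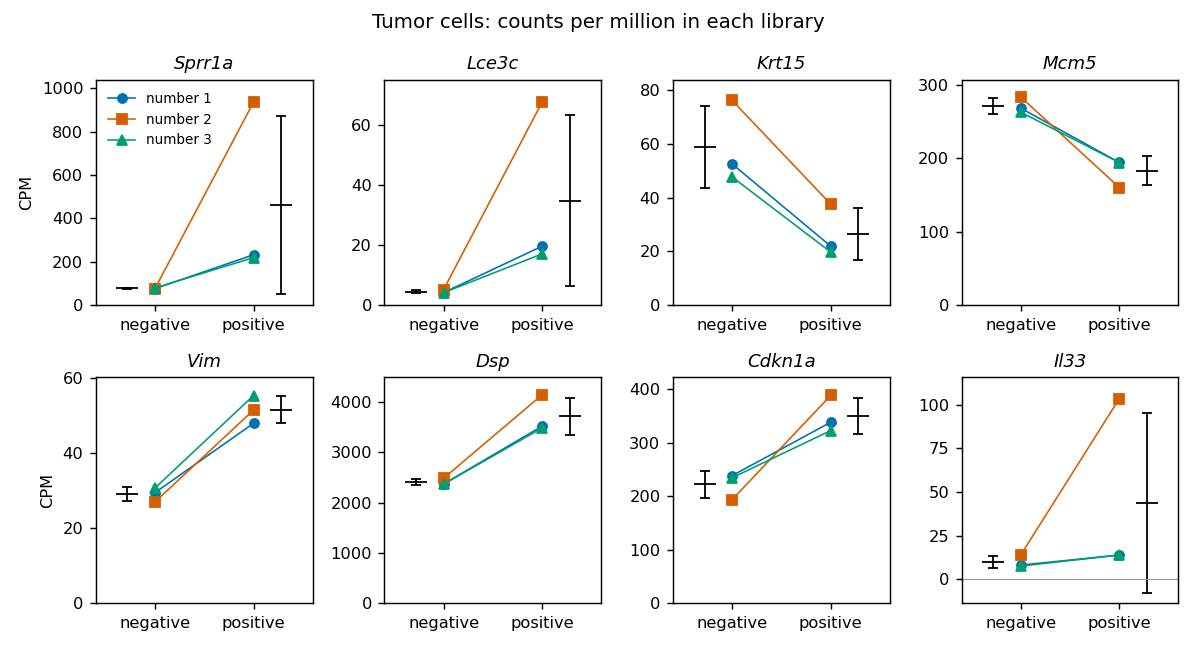
CPM per library of 8 named genes in reporter-negative and reporter-positive tumor cells, with lines joining libraries of one replicate number and black bars at the mean ± SD (n = 3). Il33 reaches 103 CPM in positive replicate 2 and is at 14.0 CPM or below in the other libraries, while Vim rises from 29.0 to 51.6 CPM on average.

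The macrophage comparison asked how macrophages with surface FceRIa differ from those without it in the same kind of tumor. Genes of resident-type macrophages, of lysosomes and of IgG receptors were higher in the FceRIa-positive macrophages, and genes of dendritic cells, antigen presentation and cell division were lower. These were calls of lists with a preset correlation, and with an estimated correlation the adjusted p was 0.207, 0.211, 0.211, 0.207, 0.302 and 0.302 in that order, while 0 genes passed over all genes in the unpaired edgeR fit. Cd163, a scavenger receptor for haptoglobin-hemoglobin complexes, was at 173 ± 122 CPM in the positive and 14.5 ± 9.45 CPM in the negative macrophages (SD, n = 3), and Mrc1, the mannose receptor, was at 2947 ± 882 against 993 ± 228 CPM. The cell adhesion gene Epcam was at 31.1 ± 15.5 CPM in the positive and 306 ± 196 CPM in the negative macrophages. The mRNA of Fcer1a itself was at or near the floor in both groups.

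At an adjusted p under 0.05 the unpaired edgeR fit called 0 genes higher and 0 lower, and its smallest adjusted p was 0.0585. At an unadjusted p under 0.05 it had 2345 genes, 1243 higher and 1102 lower, and DESeq2 without pairing called 581 higher and 611 lower. The paired fit called 1618 higher and 1524 lower. In 3204 genes (21.4%) the groups did not overlap, where chance gives 10% for libraries not tied by number. The 3 other splits that part all pairs gave 1.8% to 2.1%, while a split that keeps pairs 2 and 3 whole, and so measures the difference between replicates, gave 23%. As in the tumor cells, the 3 splits mix the groups on each side, so their low shares are no measure of chance. The paired counts were 626 higher and 691 lower without pair 1, 1298 and 1374 without pair 2 and 1743 and 1606 without pair 3. All gene calls below are therefore from the paired fit unless stated, and none of these genes passed over all genes in the unpaired fit. In the simulation the paired fit made a larger share of false calls than its threshold allows.

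Because the unpaired fit called no gene, the size rule was applied to the paired fit after seeing the data. Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799), a chemokine, rose by 4.42 ± 0.45 on the log2 scale (SE, adjusted p = 0.000633), from 16.4 ± 16.7 to 266 ± 86.4 CPM, and by 5.07 without pair 2 and 3.75 without pair 3. Folr2 (ENSMUSG00000032725, chromosome 7, 101839988 to 101857194), a folate receptor of resident macrophages, rose by 3.71 ± 0.33 (adjusted p = 0.000386), from 1.48 to 19.5 CPM. Igf1, a growth factor, rose by 3.67 ± 0.33 (4.38 without pair 2) and Vcam1, an adhesion molecule, by 3.08 ± 0.35. Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527) rose by 3.60 ± 0.50 (adjusted p = 0.00213), and without pair 1 its adjusted p was 0.0533, while without pair 2 it rose by 4.51. The other higher genes named by the rule were Pmp22, Adcy3 and Cbr2. H2-M5 (ENSMUSG00000024459, chromosome 17, 36984061 to 36989537), a non-classical class I histocompatibility gene, fell by 6.09 on the log2 scale (SE 0.32, adjusted p = 6.79e-05), from 38.4 ± 31.7 to 0.522 ± 0.306 CPM, and by 6.72 on the log2 scale without pair 1. Cldn1 (ENSMUSG00000022512, chromosome 16, 26356642 to 26371841), a claudin of tight junctions, fell by 4.45 (SE 0.22, adjusted p = 5.71e-05), from 150 to 6.19 CPM. Ccl22, a chemokine ligand of CCR4, fell by 3.66 (SE 0.15, adjusted p = 2.54e-05), and Ly75, an endocytic receptor of dendritic cells, fell by 3.94, and by 4.66 without pair 1. Cyp4f37, P2rx2, Lpar3 and Trp53i11 completed the 8 lower genes. In the unpaired fit the adjusted p of these 16 genes ranged from 0.0585 to 0.0745.

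Of the 26 lists fixed for the macrophages, camera called 15 in the unpaired fit, 6 up and 9 down. In the resident-type macrophage list, 16 of 17 tested genes were higher when adjusted over the list alone and 16 rose in the paired fit (median 1.28, camera adjusted p = 1.57e-22, adjusted p = 0.207 with an estimated correlation). Lyve1, a hyaluronan receptor, rose by 4.39 ± 0.39 from 0.877 to 17.9 CPM (5.23 without pair 2), Mrc1 by 1.56 ± 0.16 and Mertk, a receptor for the engulfment of dead cells, by 1.19 ± 0.10. In the lysosome and lipid list, 13 of 20 were higher when adjusted over the list alone and 15 rose (median 0.70, camera adjusted p = 2.53e-16, adjusted p = 0.211 with an estimated correlation). The cathepsin gene Ctsb rose by 1.19 ± 0.16, from 3078 to 6877 CPM, and the cholesterol exporter gene Abca1 by 1.52 ± 0.12. All 5 Fc gamma receptor genes were higher when adjusted over the list alone and in the paired fit (median 0.76, camera adjusted p = 2.25e-06, adjusted p = 0.211 with an estimated correlation). Fcgrt, the neonatal Fc receptor, rose by 1.48 ± 0.16 and the inhibitory receptor gene Fcgr2b by 0.78 ± 0.12. Reads shared between Fcgr2b, Fcgr3 and Fcgr4, which are similar in sequence, could not be told apart here.

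In the matrix and protease list, 5 of 18 genes were higher when adjusted over the list alone and 9 rose (median 0.39, camera adjusted p = 0.000163, adjusted p = 0.365 with an estimated correlation). Timp2, a metalloproteinase inhibitor, rose by 1.33 ± 0.14 and the collagenase gene Mmp13 by 1.26 ± 0.11. The alternative activation list moved in both directions. Adjusted over the list alone 6 of 20 were higher and 3 lower, and in the paired fit 10 rose and 5 fell (median 0.46, camera adjusted p = 0.00728, adjusted p = 0.365 with an estimated correlation). It shares Cd163, Folr2 and Mrc1 with the resident-type list, and its lower genes included Ccl22. Its call was lost without negative replicate 2 (camera adjusted p = 0.136) or positive replicate 3 (0.0703). Of the 12 macrophage markers, 5 were higher when adjusted over the list alone and 9 rose (median 0.53, camera adjusted p = 5.65e-08, adjusted p = 0.211 with an estimated correlation). Lyz2, the gene of lysozyme, was up by 0.94 ± 0.15 and Cd68 by 0.90 ± 0.11. The marker list shares C1qa, C1qb, C1qc and Mertk with the resident-type list, Fcgr1 with the Fc gamma receptor list and Cd68 with the lysosome list. Beside these higher groups, markers of dendritic cells, T and NK cells, keratinocytes, mast cells, basophils, monocytes and neutrophils were lower in the positive libraries, with the values given next.

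**Figure D3:**
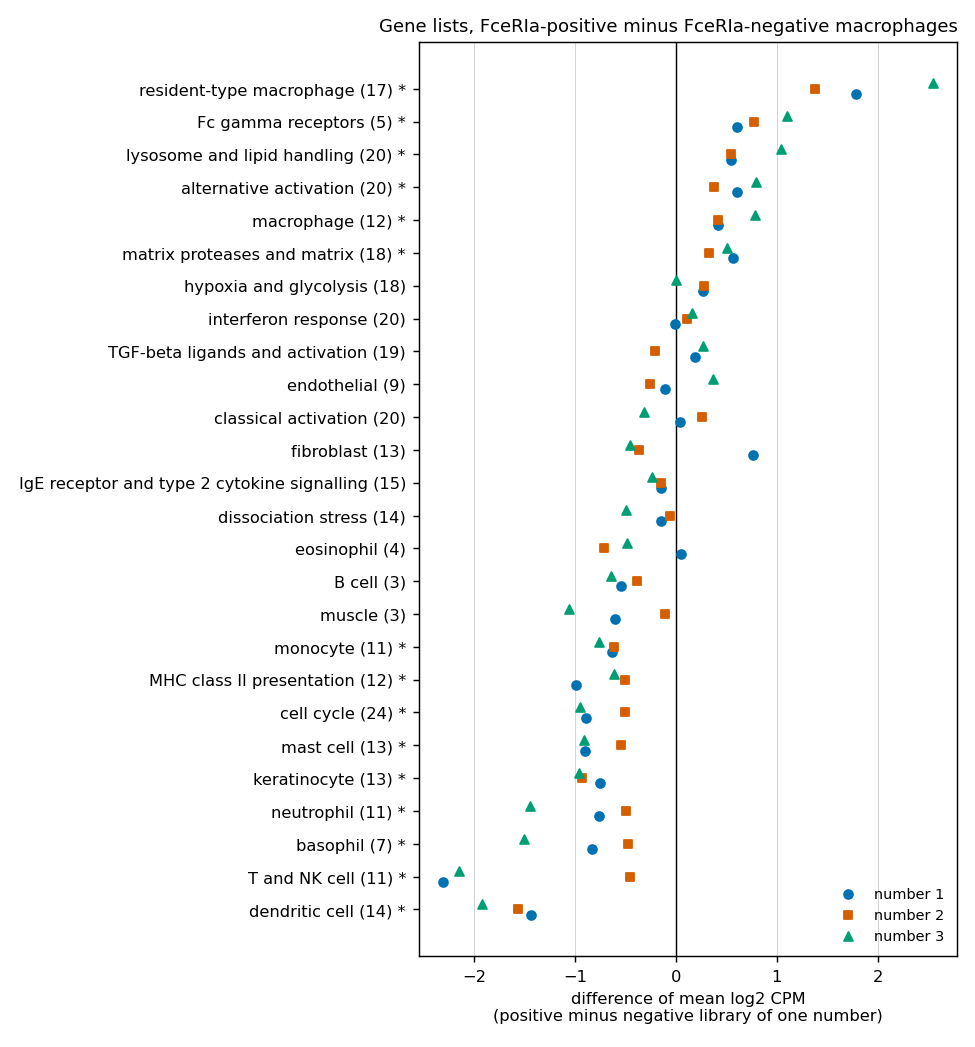
Difference of mean log2 CPM between the FceRIa-positive and the FceRIa-negative macrophage library of one replicate number, for each fixed gene list, with 3 points per list and the number of tested genes in brackets. An asterisk marks a camera adjusted p under 0.05 in the unpaired fit. The resident-type list lay at 1.79, 1.38 and 2.55 in replicates 1, 2 and 3, and the dendritic cell list at -1.44, -1.56 and -1.92.

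Of the 14 dendritic cell markers, 8 were lower when adjusted over the list alone and 10 fell in the paired fit (median -1.81, camera adjusted p = 3.89e-13, adjusted p = 0.207 with an estimated correlation). Flt3, a growth factor receptor of dendritic cell precursors, fell by 2.85 on the log2 scale (SE 0.22), and Itgae, the integrin alpha E chain, fell by 2.69 (SE 0.30). Of the 12 genes of MHC class II presentation, 4 were lower when adjusted over the list alone and 8 fell (median -0.64, camera adjusted p = 1.61e-06, adjusted p = 0.302 with an estimated correlation). Ciita, the transcriptional activator of these genes, fell by 0.85 (SE 0.10), from 499 ± 68.2 to 281 ± 67.1 CPM, and H2-Oa fell by 1.82 (SE 0.17). Of 24 cell cycle genes, 16 were lower when adjusted over the list alone and 23 fell (median -0.83, camera adjusted p = 1.13e-19, adjusted p = 0.302 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell by 1.22 (SE 0.10), from 30.4 to 12.9 CPM.

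Of the 13 keratinocyte markers, 2 were lower when adjusted over the list alone and 12 fell in the paired fit (median -0.57, camera adjusted p = 0.00518, adjusted p = 0.445 with an estimated correlation). The call was lost without negative replicate 1 (camera adjusted p = 0.147) or positive replicate 3 (0.313). Epcam (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129) fell by 3.24 on the log2 scale (SE 0.13, adjusted p = 1.96e-05) and Cdh1, the gene of E-cadherin, fell by 2.06 (SE 0.10), from 949 to 221 CPM. The keratin Krt5 fell by 0.59 (SE 0.08). Of 11 T and NK cell markers, 1 was higher and 7 lower when adjusted over the list alone, and 1 rose and 8 fell in the paired fit (median -2.31, camera adjusted p = 0.000887, adjusted p = 0.302 with an estimated correlation). The higher gene was Cd4, a T cell coreceptor that myeloid cells also express, which rose by 1.51 ± 0.13 from 50.9 to 141 CPM, while Cd3g fell by 4.16 (SE 0.52), from 10.4 to 0.528 CPM, and by 3.24 without pair 1. Of 11 monocyte markers, 1 was higher and 2 lower when adjusted over the list alone, and 1 rose and 8 fell (median -0.63, camera adjusted p = 0.00312, adjusted p = 0.365 with an estimated correlation). The fractalkine receptor gene Cx3cr1 rose by 0.81 ± 0.15 and the chemokine receptor gene Ccr2 fell by 0.67 (SE 0.13).

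Markers of mast cells and granulocytes were lower or not called. Of 13 mast cell markers, 1 was lower when adjusted over the list alone and 5 fell in the paired fit (median -1.01, camera adjusted p = 0.00446, adjusted p = 0.365 with an estimated correlation), and Kit, the stem cell factor receptor, fell by 1.82 (SE 0.13), from 13 to 3.72 CPM. Of 7 basophil markers, 0 passed when adjusted over the list alone and 3 fell (median -1.17, camera adjusted p = 0.0154, adjusted p = 0.387 with an estimated correlation). The basophil list as fixed shares Gata2, Hdc, Ms4a2 and Cpa3 with the mast cell list. Of 11 neutrophil markers, 0 passed when adjusted over the list alone and 8 fell (median -1.18, camera adjusted p = 0.049, adjusted p = 0.594 with an estimated correlation), and Cxcr2, a chemokine receptor, fell by 1.39 (SE 0.21). The mast cell list had a camera adjusted p of 0.0502 without positive replicate 1 and the basophil list 0.191 without negative replicate 3 and 0.112 in the paired fit without pair 3. The neutrophil call was lost without negative replicate 1 (0.363), negative replicate 3 (0.262), positive replicate 2 (0.462) or positive replicate 3 (0.0858) and with DESeq2 scaling factors (0.0528). Eosinophil markers were not called as a list in the unpaired or paired fit, but were with no count filter (0.0102) and in the paired fit without pair 1 (0.018). Of 4 tested, 2 were lower when adjusted over the list alone and 2 fell with the block (camera adjusted p = 0.107).

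**Figure D4:**
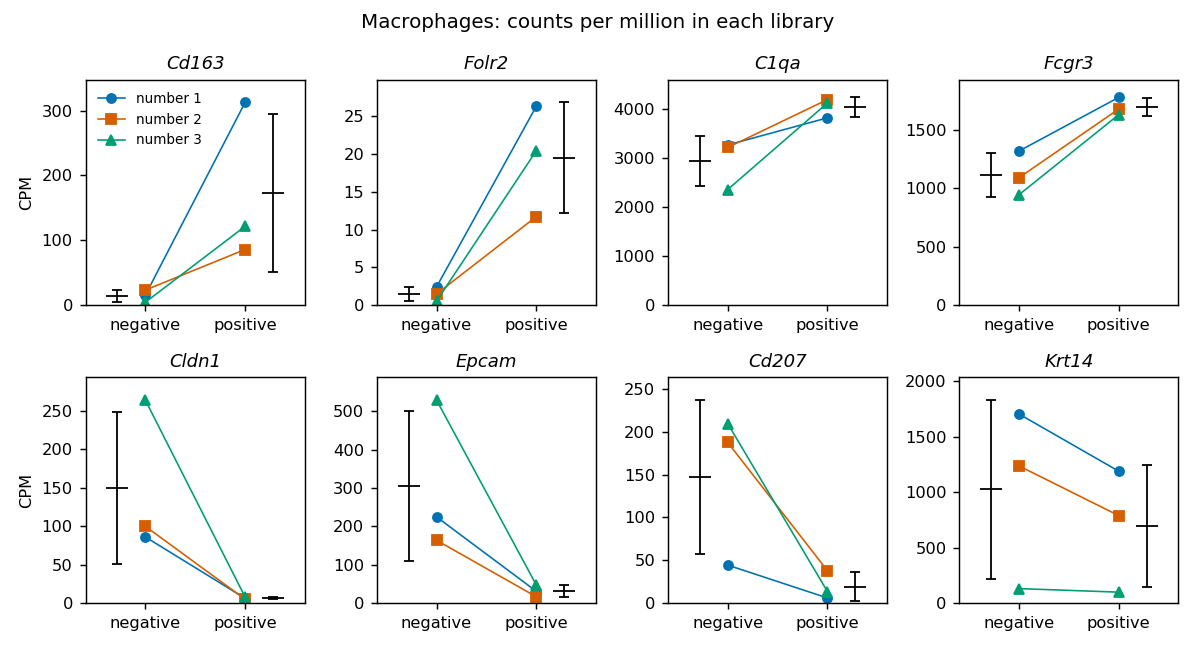
CPM per library of 8 genes in FceRIa-negative and FceRIa-positive macrophages, with lines joining libraries of the same replicate number and black bars at the mean ± SD (n = 3). C1qa, Cd207 and Krt14 fall outside the naming rule and were chosen after their values were seen. Fcgr3 averages 1691 CPM in positive and 1115 CPM in negative macrophages, and Epcam averages 31.1 and 306 CPM.

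The sort genes were read in every library. Fcer1a (ENSMUSG00000005339, chromosome 1, 173221284 to 173227214) had 0, 4 and 3 counts in the negative and 2, 7 and 1 counts in the positive replicates 1 to 3. It lay below the count filter, and no difference was detectable at this depth. Ptprc, the gene of CD45, differed by 0.07 ± 0.16 (adjusted p = 0.912). Adgre1, the gene of F4/80, was at 935 ± 41.2 CPM in the positive and 612 ± 109 CPM in the negative macrophages, and rose by 0.63 ± 0.11 in the paired fit (adjusted p = 0.00498, unpaired 0.12). Il1rl1, the receptor of IL-33, fell by 1.52 on the log2 scale in the paired fit (SE 0.17, adjusted p = 0.000879, unpaired 0.21), from 5.47 ± 2.93 to 1.89 ± 1.03 CPM. In the list of IgE receptor and type 2 cytokine signalling, 2 of 15 genes were higher and 2 lower when adjusted over the list alone, and 3 rose and 4 fell in the paired fit (camera adjusted p = 0.589). Fcer1g, the signalling chain shared by Fc receptors, rose by 0.44 ± 0.11 in the paired fit (adjusted p = 0.0274, unpaired 0.164), with adjusted p = 0.0549 without pair 1 and 0.0999 without pair 2. Ms4a2, the beta chain of the IgE receptor, went the other way and was added here after its values were seen. It had 23, 55 and 47 counts in negative replicates 1 to 3 and 11, 16 and 13 in the positive ones. Ms4a2 is also in the mast cell and basophil lists, whose markers were lower as well. Which cells the few transcripts of Il1rl1 and Ms4a2 came from was not tested. Il4ra, the shared receptor chain of IL-4 and IL-13, rose by 0.72 ± 0.08 and Il13ra1 fell by 0.44 (SE 0.09).

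The list of TGF-beta ligands and their activators was not called (camera adjusted p = 0.108), but was with no count filter (0.025) and in the paired fit without pair 2 (0.0104). Of its 19 genes 2 were higher when adjusted over the list alone, and 5 rose and 1 fell with the block, among them the receptor gene Tgfbr2, which rose by 0.70 ± 0.09 (adjusted p = 0.00148). Tgfb1 was at 318 ± 103 CPM in the positive and 271 ± 79.6 CPM in the negative macrophages (paired adjusted p = 0.0966). Of the 18 hypoxia genes 6 rose, of the 20 interferon genes 1 rose and 1 fell, and of the 20 classical activation genes 3 rose and 3 fell in the paired fit. In each of these lists 0 genes passed when adjusted over the list alone, and the camera adjusted p was 0.342, 0.524 and 0.692. Of the 14 dissociation stress genes 0 passed when adjusted over the list alone and 5 fell with the block (camera adjusted p = 0.276 without and 0.0364 with the block, adjusted p = 0.591 with an estimated correlation and the block), and the paired call was lost without pair 3 (0.233). Of the endothelial (9), fibroblast (13), B cell (3) and muscle (3) markers, 2 endothelial and 1 fibroblast marker rose and 1 fibroblast and 1 B cell marker fell in the paired fit. Adjusted over the list alone, 1 B cell marker was lower and 0 of the endothelial, fibroblast and muscle markers passed (camera adjusted p = 0.642, 0.824, 0.272 and 0.201 for endothelial, fibroblast, B cell and muscle). Among these lists, leaving out 1 library brought camera calls for the hypoxia list (0.0376 without negative replicate 1, 0.0117 without positive replicate 2), the dissociation stress list (0.000667 without negative replicate 2, 0.0299 without positive replicate 3), the interferon and fibroblast lists (0.0131 for each without positive replicate 1), the B cell list (0.0402 without negative replicate 3) and the TGF-beta list (0.0138 without positive replicate 2). In the paired fit camera called the hypoxia list without pair 3 (0.00347), the B cell list without pair 2 (0.0262) and the fibroblast list without pair 1 (0.0239). The median, mean and test differed in sign for the B cell list (median 0.24, mean -0.56, test down) and the endothelial list (median -0.10, mean -0.11, test up).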

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

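The alternatives described as added in the methods were chosen after seeing the data. In the tumor cells, against 78 genes higher and 32 lower without pairing, the counts were 635 and 350 with DESeq2, 657 and 400 at an unadjusted p under 0.01, 1450 and 999 with the replicate block, and 1027 and 659 with the block in DESeq2. With no count filter 173 were higher. The block without pair 1, 2 or 3 gave 1055, 2927 and 803 higher and 498, 2802 and 340 lower, and leaving out pair 2 without the block gave 2782 and 2619. With replicates 1 and 3 summed the counts were 0 and 0 without and 691 and 244 with the block, and with the summed libraries the unpaired fit has fewer samples. Leaving out 1 library gave 0 to 391 higher (highest without positive replicate 2) and 0 to 230 lower. Counts with other scaling factors or a mean CPM of at least 5 were within 1.5 times. In the macrophages, against 0 higher and 0 lower without pairing, the counts were 581 and 611 with DESeq2, 292 and 331 with no count filter, 552 and 480 at an unadjusted p under 0.01, 1618 and 1524 with the block, and 1433 and 1328 with the block in DESeq2. The block without pair 1, 2 or 3 gave 626, 1298 and 1743 higher and 691, 1374 and 1606 lower. Leaving out 1 library gave 0 to 0 higher and 0 to 2 lower, with 2 without negative replicate 1 and 1 without negative replicate 3. The cause of these shifts was not tested, beyond the smaller number of samples where libraries were left out or summed. For the gene lists, camera called 6 tumor and 15 macrophage lists. With a correlation estimated per list this was 0 and 0, with fry 1 and 6, and with the block 0 and 0 in both of these tests. With the block and the preset correlation 9 tumor and 16 macrophage lists were called. The block added the cytokine, leukocyte and dissociation stress lists in the tumor cells and the dissociation stress list in the macrophages, and changed no other list call. With no count filter 6 and 17 were called. Without 1 library 5 to 8 tumor and 13 to 16 macrophage lists were called.

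Of 2449 tumor genes called with the block, 1342, 2435 and 1073 were still called without pair 1, 2 and 3, and of 3142 macrophage genes 1262, 2394 and 2724. Without pair 2 the tumor spread is that between replicates 1 and 3, which were close to each other. Of 20 named tumor genes called without pairing, 20 lost the call without negative replicate 1 or 3 or positive replicate 1 or 3, 18 without negative replicate 2 and 0 without positive replicate 2. With DESeq2 scaling factors 2 of the 20 lost it and with upper-quartile factors 3. Of the 109 named macrophage genes 92 gained a call with the block and of the other 64 tumor genes 45 did. Without pair 1, 2 or 3 the paired fit called 69, 90 and 90 of these macrophage genes and 41, 53 and 38 of these tumor genes. With replicates 1 and 3 summed in the paired fit 36 of these 45 were called and 9 were not, and none of these 9 is described in the results. Under the alternatives run, 0 named genes reversed, where a change of sign counted only if the gene was called in the unpaired edgeR fit or in the alternative. Changes of sign in genes called in neither were not counted. Depth limits Fcer1a, with 7 counts at most. The pseudocount and filter alternatives planned for normalized values were not run, because the tables hold counts.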

Other observations

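All tests of explanations in this part were chosen after the results were seen. The sex-linked genes were read in all 12 libraries as a check of the mice behind them. The tumor libraries had 0 to 5 counts of Xist, the RNA of the inactive X chromosome, and 886 to 1459 counts of the Y-linked gene Ddx3y. In the macrophages the pattern followed the replicate number. Negative and positive replicate 1 had 8506 and 12096 counts of Xist with 1287 and 1584 of Ddx3y, so transcripts of both sexes were present. Replicate 2 had 4 and 6 of Xist with 5972 and 4817 of Ddx3y, and replicate 3 had 16108 and 18122 of Xist with 3 and 6 of Ddx3y. Eif2s3y and Kdm5d followed Ddx3y.

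Other gene groups were described by single genes of the fixed lists. In the paired macrophage fit Arg1, the arginase of alternatively activated macrophages, rose by 2.28 ± 0.09 (edgeR adjusted p = 1.84e-05), from 39.6 ± 32.5 to 189 ± 159 CPM (n = 3), with an unpaired adjusted p of 0.323. Il10, an anti-inflammatory cytokine, rose by 1.6 ± 0.24 from 1.11 to 3.33 CPM, and Stab1, a scavenger receptor, rose by 1.86 ± 0.19. The eosinophil marker listed as Siglec5 fell by 1.35 on the log2 scale (SE 0.14), from 16.5 to 6.35 CPM. These genes were picked after their values were seen. In the tumor cells, Areg, an EGF receptor ligand, was at 718, 207 and 667 CPM in negative replicates 1 to 3 and at 763, 275 and 765 CPM in positive replicates 1 to 3.

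Epcam, Cdh1 and Cldn1 were lower in FceRIa-positive macrophages in each pair. If the cause were more RNA of basal tumor cells in the negative libraries, Krt14 would drop far more than these genes. It lies at least 112 times above each of them in the tumor libraries. The highest ratio of the Krt14 drop to the drop of one of these genes was 6.46, and in replicate 3 the negative library had 129 CPM of Krt14 with 529 CPM of Epcam. These values argue against RNA of such cells. Keratinocytes other than the sorted basal tumor cells were not sequenced, so the test does not cover them. More dendritic or Langerhans-type cells in the negative libraries may contribute, as the langerin gene Cd207 fell by 3.06 in the paired fit, from 147 to 18.9 CPM. The mean of the dendritic cell list was lower in each pair (log2 differences of -1.44, -1.56 and -1.92). Fry called that list without the block (adjusted p = 0.0276) but not with it (0.0515). Its camera adjusted p of 0.207 with an estimated correlation cannot decide this, since 0 lists were called that way. Dendritic or Langerhans-type cells, RNA of other keratinocytes, and a change within macrophages that goes with FceRIa stay open. The CD45 sort would remove keratinocytes but not dendritic cells, yet Krt14 was present, at 129 CPM in negative replicate 3. The mean log2 CPM of the 13 keratinocyte markers was 7.59, 7.09 and 4.97 in negative replicates 1 to 3 and 6.83, 6.15 and 4.01 in the positive ones. These markers include Epcam and Cdh1, so their mean does not by itself show keratinocyte RNA. With Krt14 present, the sort does not weigh against keratinocyte RNA here.

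The resident-type genes were higher in the FceRIa-positive libraries, while markers of 7 other cell types were lower, among them the mast cell and basophil lists, which share genes. These were list calls with a preset correlation. With an estimated correlation the adjusted p was 0.207 for the resident-type list and 0.207 to 0.594 for the 7 others, and the keratinocyte, mast cell, basophil and neutrophil calls were lost in the unpaired fit with 1 library left out. Fewer cells of other types in the positive libraries would raise macrophage genes by about 1 factor, and C1qa, C1qb and C1qc rose by at most 0.93 on the log2 scale at their upper bound (2 SE). Of the 14 other resident-type genes, 9 lay above that bound by their own 2 SE, which argues against dilution as the whole cause. A share of it may remain, and so may a different mix of macrophage types, which was not tested.

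Il33 rose by 89.4 CPM from negative to positive tumor replicate 2. Fibroblasts, leukocytes, endothelial cells or muscle in that library would bring their own transcripts. The largest rise of any gene of these 4 marker lists was 13.5 CPM, for Col3a1. The ratio of these markers to Il33 in such cells was not measured, so this test cannot decide whether they contributed. The sort for YFP and integrins would remove such cells, but their transcripts were present in that library (Col1a1 at 56.2 CPM and Cd74 at 56.2 CPM), so the sort by itself does not exclude them. The keratinocyte differentiation list differed by 1.96 (mean log2) in pair 2 and by 0.95 and 0.93 in pairs 1 and 3, so more differentiated tumor cells in that library may go with the Il33 level. This is 1 library, and a response to TGF-beta in these cells stays open as well, untested.

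The 6 libraries of a comparison can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. In the tumor cells 1 of the 10 splits called 110 genes, the real one, and the highest of the others called 0. With the block, 4 splits part all 3 pairs. Of these, 1 called as many as the real one with its 2449 genes, and the highest other called 0. In the macrophages all 10 splits, the real one included, called 0 genes without the block. With the block 1 of 4 called as many as the real 3142, and the highest other called 0. Every split other than the real one mixes the groups on each side, so a real group difference adds to its spread. The 0 calls of these splits therefore do not show how many genes chance would call.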
